A study of Homo sapiens with 3 samples.

How the data were processed

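Gene expression was measured with Affymetrix human expression arrays in a colorectal cancer cell line, with 3 arrays and 1 array per group. The groups are cells infected with an empty-vector virus (control), with a virus carrying full-length LATS2, a serine/threonine kinase of the Hippo pathway (LATS2), and with a virus carrying residues 1 to 625 of LATS2 (LATS2N). The sample labels name the line SW620, a line grown from a lymph node metastasis, while the series design text names SW480, a line grown from the primary tumour of the same patient; the values were not used to decide between them. Per the labels' protocols, cells were grown in serum-containing medium, total RNA was extracted with a column kit, and biotin-labelled cRNA was made by the manufacturer's standard protocol.

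The values analysed here are the deposited probe set intensities, on a linear scale, made with MAS5 per the submitters' processing notes, which give no version or settings. The mean of each array without its lowest and highest 2% of values came to 500.1 on all 3 arrays, found from the values, so each array had been scaled to a common target of 500 and was not otherwise normalised between arrays as far as the values show. The median signal was 51.1 on the control array, 49.4 on the LATS2 array and 51.0 on the LATS2N array. No detection calls were analysed here. The number of arrays limits the precision, and with 1 array per group there are no replicates, no spread between replicates and no replicate check of any difference.

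Each array holds 54675 probe sets, of which 62 are the manufacturer's controls. The platform's probe table gave exactly 1 gene symbol for 41091 of the others and several for 1801, and it did not list 11721. Symbols were updated through the gene identifiers to the RefSeq gene table of assembly GRCh38.p14, which matched 41037 of the probe sets with 1 symbol. A gene was represented by its probe set with the highest mean log2 signal over the 3 arrays, which gave 19775 genes, 9252 of them with 1 probe set. Probe sets with several symbols or none were left out of the gene results.

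Signals below a floor, the median signal over all probe sets of the 3 arrays (50.5), were set to the floor before log2 ratios were taken. A gene was called higher or lower by size alone, when its floored signals differed by at least 2-fold between 2 arrays. No test, p-value or standard deviation between samples exists for such a call. Where 1 of the 2 arrays is at the floor, the ratio is a bound and is written "at least". The spread within an array was estimated from the pairs of probe sets for 1 gene: between LATS2 and control, the robust SD of a log2 ratio was 0.42 where the dimmer signal lay between 50 and 100, 0.30 between 100 and 200, 0.24 between 200 and 500, 0.17 between 500 and 2000, and 0.11 above 2000. This spread covers noise between probe sets, not differences between cultures.

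The 3 comparisons were: LATS2 against control, LATS2N against control, and LATS2 against LATS2N. The comparisons, the size call, the floor, most alternative settings, 20 gene lists and the rule for naming genes were fixed before the data were examined. List members without a probe set of exactly 1 symbol were not analysed here. For each list, the median log2 ratio was taken over the other members whose brighter array reached the floor, and its percentile was found among 10000 random lists of the same size drawn from the same 20 bins of mean signal. These percentiles are a description of these arrays and not p-values. The genes named are LATS2 on every array; per comparison, the 10 with the largest and the 10 with the smallest ratio among called genes with both signals above the floor and all usable probe sets in the same direction; every called Wnt or YAP target and up to 4 called members of each other list in a construct against control; and up to 10 genes per direction called in both constructs. The genes called in both constructs also had to have signals above the floor and usable probe sets in the same direction. Other genes are named as members of a list or are said to have been chosen after their values were seen.

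LATS2 against control and LATS2N against control use the same control array. Unchanged arrays that share a control were therefore simulated 100 times, from each probe set's mean signal with the spread between probe sets as noise, and the control array cannot be split. That noise was taken from LATS2N against control and leaves out differences between cultures, so real unchanged arrays may vary more. The calls were tested on simulated data of the 19775 genes, in 20 sets, with 200 genes shifted in the LATS2 array against control. The shifted genes were drawn only from the 11535 genes above the floor on all 3 arrays. The shares called below therefore do not cover genes at the floor. Of the genes shifted 3-fold, 95.1% were called, of those shifted 2-fold 50.6%, and of those shifted 1.5-fold 1.9%. The median shift of a list of 16 genes raised 1.5-fold lay above the middle 95% of the random lists in 20 of 20 sets.

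Alternatives changed 1 choice at a time: centred arrays, quantile normalisation, a floor at the 25th or the 75th percentile, no floor with 16 added to each signal, the median over a gene's probe sets, leaving out probe sets whose names mark possible shared targets, calls at 1.5-fold or 3-fold, and calls only where 2 probe sets each pass. A minimum signal of 500, and the settings for list medians of LATS2 against LATS2N, were added after seeing the data. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.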

Results

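The 3 arrays profiled a colorectal cancer line carrying an empty vector, full-length LATS2, or residues 1 to 625 of LATS2 (LATS2N), which end before the kinase domain at the C-terminus. The labels give each construct as overexpressed, and the series title asks which genes LATS2 regulates in colon cancer cells. The share of probe sets above the floor of 50.5 was 50.2% on the control, 49.6% on the LATS2 and 50.2% on the LATS2N array. The floor is the median of these same signals, so the level of these shares was fixed by it and is no detection rate. Over 9 probe sets for the manufacturer's hybridisation spike-ins, the median log2 ratio was 0.01 for LATS2 against control (from -0.31 to 0.36) and 0.09 for LATS2N (from -0.06 to 0.35). Over the 9 other probe sets for the same spike-ins it was 0.08 for LATS2 (from -0.19 to 0.17) and 0.20 for LATS2N (from -0.08 to 0.53). The ratio of the 3-prime to the 5-prime signal of GAPDH was 1.02 on the control, 0.94 on the LATS2 and 0.96 on the LATS2N array, and that of ACTB was 1.68, 1.74 and 1.85. The 18S ribosomal RNA probe sets were brightest on the control array. Their median over 3 probe sets was 2.48-fold lower on the LATS2 array and 1.63-fold lower on the LATS2N array.

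LATS2 itself was measured by 4 probe sets, and none showed a raised transcript above the floor. One probe set read 205.7 on the control, 219.2 on the LATS2 and 219.1 on the LATS2N array, and another read 385.2, 377.1 and 409.2. The other 2 stayed at or below the floor on every array. Which part of the LATS2 transcript these probe sets read is not known here, and a probe set outside the cloned sequence would not see the construct, so these values neither check nor contradict the labels. The arrays are therefore named below by their labels.

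The array labelled full-length LATS2 was compared with control to ask which genes differ between them. Among genes with a signal of at least 500 on 1 of the arrays compared, the lowest ratio was that of FGD2, a guanine nucleotide exchange factor, at least 9.97-fold lower than on the control array and at the floor on the LATS2 array, followed by the sialyltransferase gene ST3GAL3, 7.58-fold lower with probe sets that disagreed. Both fall outside the naming rule and were chosen after their values were seen. Among the genes of the rule, ANKRD37, a target of the hypoxia-inducible factor, was 3.58-fold lower (1414 against 5060), DDIT4, an inhibitor of mTORC1 signalling induced by hypoxia and stress, was 3.50-fold lower (3117 against 10901), and ADM, which encodes the vasodilator peptide adrenomedullin, was 3.26-fold lower. TNC, which encodes the matrix protein tenascin C, was 2.93-fold lower (1241 against 3636), and TAGLN, an actin-binding protein, was 3.35-fold lower. The rule's highest genes on the LATS2 array against control included the cancer-testis genes SPANXB1, 3.87-fold higher, and MAGEA12, 3.11-fold higher, and HSPA6, an inducible heat shock gene, 3.01-fold higher. All 3 of these higher genes read below 400 on every array. The fixed heat shock list, which does not include HSPA6, was not higher on the LATS2 array. Its median log2 ratio against control was -0.06 at percentile 6.98, with none of 7 measured members called.

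By the size call, 127 genes were higher and 111 lower on the LATS2 array than on the control array, out of 13187 genes that reached the floor. Both signals were above the floor for 95 of the higher and 74 of the lower genes. With a signal of at least 500 on the brighter array, a limit chosen after seeing the data, 17 were higher and 27 lower. Simulated unchanged arrays gave a mean of 21.7 higher and 22.5 lower calls. They hold only noise between probe sets and no differences between cultures, so these means are not a rate of false calls. The remaining lowest genes under the naming rule were ZNF800, 3.53-fold, SLCO1B3, a liver-type organic anion transporter, 3.14-fold, CD300LG, 3.09-fold, RARRES2, which encodes the chemoattractant chemerin, 3.0-fold, and HSD11B2, which inactivates cortisol, 2.95-fold. The remaining highest genes were LINC00520, DTNB, PPFIBP2, ASCL5, CCDC24, TMEM92 and ADAMTS17, between 2.82-fold and 3.84-fold. Chosen after their values were seen, the bright higher genes included DKK4, a secreted Wnt antagonist (15957 against 7523, 2.12-fold), the transcription factor ETV1 (2.51-fold, 5 probe sets in the same direction) and the protocadherin PCDH19 (2.47-fold), and the bright lower genes included ABAT, a GABA transaminase (2.69-fold), and TM4SF1, a membrane protein (2.73-fold).

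The hypoxia and glycolysis list was lower on the LATS2 array than on control. Of its 18 fixed members 17 had a probe set with 1 symbol, and of the 16 that reached the floor, 5 were called lower and none higher, 13 had a ratio below 0, and the median log2 ratio was -0.57, below all 10000 matched random lists. With the median over probe sets in place of the brightest probe set, the list median was -0.32. Besides ANKRD37 and ADM, the called genes were EGLN3, an oxygen-sensing hydroxylase, 2.42-fold lower, PFKFB3, a regulator of glycolysis, 2.29-fold lower, and, named after its value was seen, VEGFA, the angiogenic growth factor, 2.21-fold lower with probe sets that did not all go the same way. The glycolytic enzymes of the list did not all behave alike: HK2, a hexokinase, was 1.97-fold lower (2970 against 5853) and short of the call, while the log2 ratios were 0.07 for PGK1, -0.04 for LDHA, 0.12 for ENO1 and 0.02 for ALDOA. On the LATS2N array the same list was slightly higher than on control, with a median of 0.15 at percentile 99.4, and no member was called. Without probe sets of possible shared targets that median was 0.28. Not every member was higher there: 3 were below control, VEGFA, HK2 and PFKFB3, with log2 ratios of -0.45, -0.33 and -0.14.

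Genes of sterol and fatty acid synthesis were also lower on the LATS2 array. Only 16 of the 22 fixed members had a probe set with 1 symbol, and the other members were not analysed here. Of these 16, 15 had a ratio below 0 and 3 were called lower, and the median was -0.64, below all random lists. INSIG1, a regulator of sterol synthesis that is itself induced when sterols are low, was 2.596-fold lower (308 against 798), MVD, a mevalonate pathway enzyme, was 2.26-fold lower, and IDI1, another enzyme of that pathway, was 2.01-fold lower with probe sets that did not all go the same way. On the LATS2N array 15 of the 16 were again below 0, with a smaller median of -0.27 at percentile 0.01 and no calls. The 18S ribosomal RNA probe sets were also lower on both construct arrays in the same order, with median log2 ratios of -1.31 for LATS2 and -0.70 for LATS2N against control.

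The NF-kB and inflammatory list was lower on the LATS2 array and higher on the LATS2N array. Of 17 fixed members 16 had a probe set with 1 symbol. Of the 13 that reached the floor on the LATS2 or control array, 11 had a ratio below 0 and 2 were called lower, TNFAIP2 by 2.08-fold and the chemokine CCL20 by 2.02-fold (1446 against 2915), and the list median was -0.55. Of 14 members on the LATS2N array, 11 had a ratio above 0 and 1 was called, IL1B, a pro-inflammatory cytokine, 2.15-fold higher, and the list median was 0.43. The first median lay below all random lists and the second above all of them. The chemokine gene CXCL1 read 3458 on control, 2411 on LATS2 and 5658 on LATS2N, and CXCL8 read 1014, 680.0 and 1547. Not every member changed direction between the constructs. IL1B and ICAM1 were above control on both arrays, with log2 ratios of 0.61 and 0.28 on the LATS2 array. RELB, NFKB2 and SOD2 were below control on both, with -0.19, -0.36 and -0.20 on the LATS2N array.

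**Figure D1:**
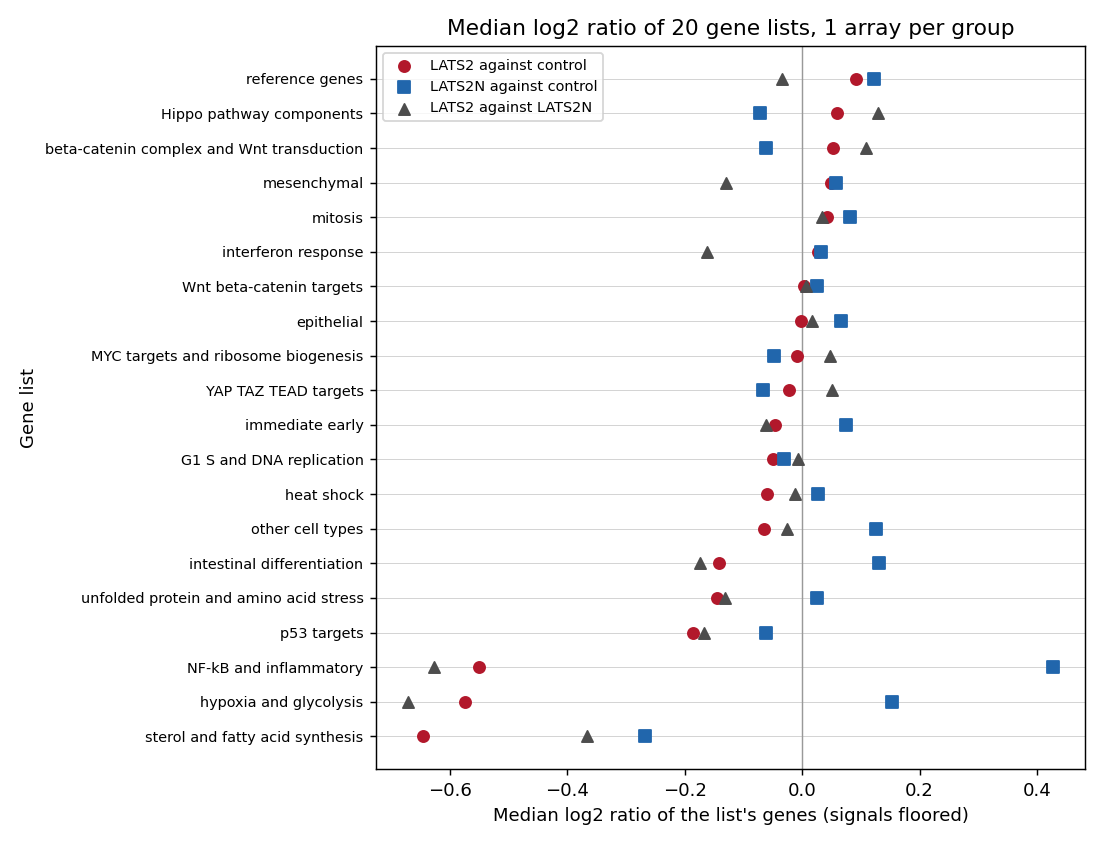
Median log2 ratio (horizontal axis) of each of the 20 gene lists (vertical axis) for LATS2 against control (circles), LATS2N against control (squares) and LATS2 against LATS2N (triangles), 1 array per group. The hypoxia, NF-kB and sterol lists lie at -0.57, -0.55 and -0.64 for LATS2 against control, and the Wnt and YAP target lists lie near 0.

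Targets of the beta-catenin pathway and of YAP and TAZ, the transcriptional coactivators that Hippo signalling restrains, did not stand apart as lists. A probe set with 1 symbol was present for 27 of the 30 fixed Wnt targets and 22 of the 24 fixed YAP and TAZ targets. Of 26 Wnt targets on the LATS2 array, 1 was called higher, the growth factor gene FGF18 (2.40-fold, 515 against 214), and 1 lower, the receptor gene TNFRSF19 (2.07-fold, 343 against 711). The list median was 0.00 at percentile 31.6, and on the LATS2N array it was 0.03 at percentile 56.3 with no calls. AXIN2 had log2 ratios of 0.05 and -0.01 on the LATS2 and LATS2N arrays, MYC 0.22 and 0.22, and CCND1 -0.12 and -0.30. Of 17 YAP and TAZ targets on the LATS2 array, 1 was called higher, CCN1, 2.04-fold (136.3 against 66.8), and the median was -0.02 at percentile 25.5, which turned to 0.10 at a floor at the 25th percentile and 0.076 with no floor. For LATS2N that median was -0.07 at percentile 15.9, with no calls. Many YAP and TAZ targets were dim, and only 8 read at least 500 on any array. ANKRD1 was below the floor on every array. CCN2 read 28.6 on the control, 66.4 on the LATS2 and 38.8 on the LATS2N array. The medians of this list therefore cannot show that YAP and TAZ output was unchanged. Among components of the Hippo pathway, TEAD3 was called higher on the LATS2 array, 2.05-fold at signals of 77.8 and 159.6, while YAP1 had log2 ratios of -0.12 and -0.09.

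Cell cycle lists differed little. The mitosis list had medians of 0.04 and 0.08 on the LATS2 and LATS2N arrays, at percentiles 67.3 and 92.6, and the list of G1/S and DNA replication genes had medians of -0.05 and -0.03, at percentiles 3.84 and 5.27, with no calls in either. The p53 target list was lower on the LATS2 array, with 14 of 16 members below 0 and a median of -0.19 at percentile 0.24, and its median on the LATS2N array was -0.06. No p53 target was called against control, while PHLDA3 was called 2.66-fold lower in LATS2 against LATS2N, and CDKN1A, a cell cycle inhibitor, had log2 ratios of -0.68 and -0.67 against control. The list of unfolded protein and amino acid stress genes had a median of -0.15 at percentile 0.10 on the LATS2 array, where DDIT4 was its only called member, and 0.02 on the LATS2N array. Markers of other cell types had medians of -0.07 and 0.13 over 9 members, with 1 called, ACTA2, at least 2.04-fold higher on the LATS2 array.

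**Figure D2:**
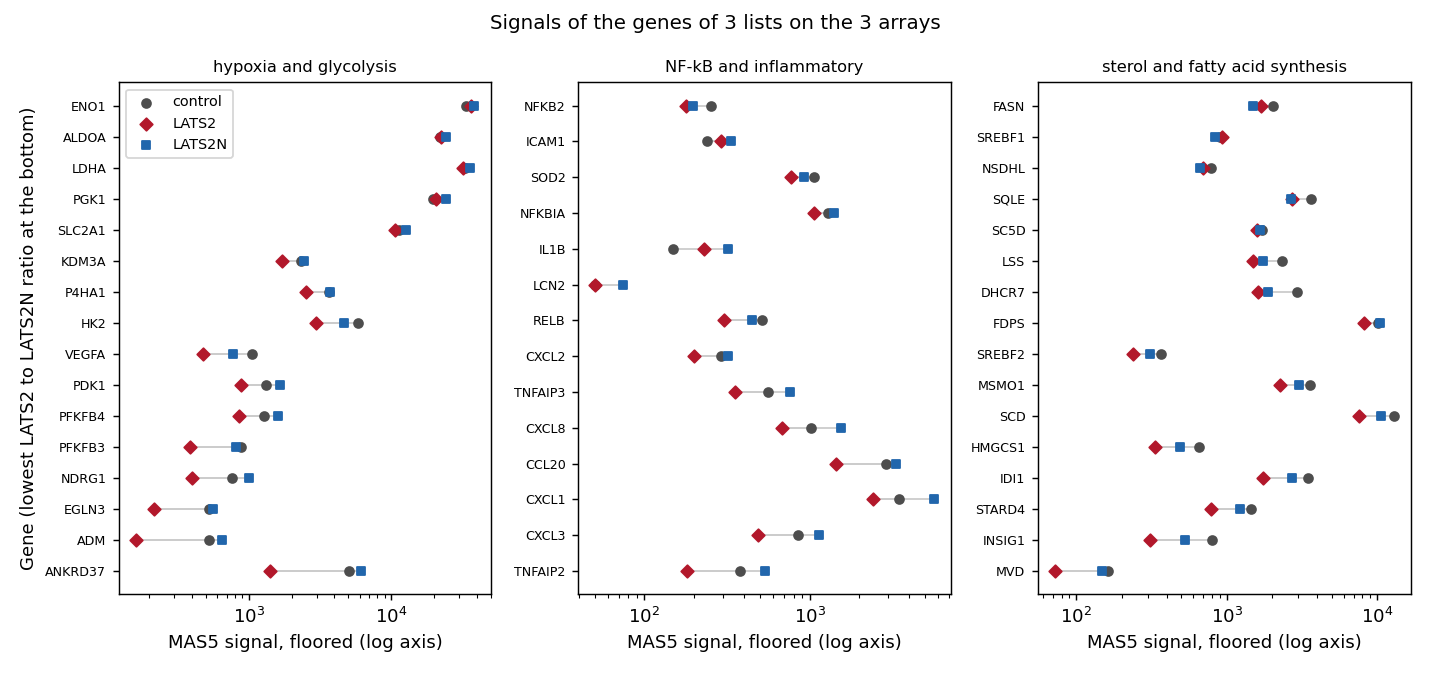
Signals (horizontal log axis, signals below the floor drawn at the floor) of the genes of the hypoxia, NF-kB and sterol lists on the control (circles), LATS2 (diamonds) and LATS2N (squares) arrays, 1 array per group. ANKRD37, at the bottom of the first panel, reads 5060, 1414 and 6147 on the control, LATS2 and LATS2N arrays.

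The LATS2N array was compared with control to ask which genes differ with the fragment that lacks the kinase domain. Under the naming rule, the genes highest on the LATS2N array were FABP3, a fatty acid carrier, 3.35-fold higher than on control, IRAK2, a kinase of interleukin-1 receptor signalling, 3.25-fold higher, LZTS3, 3.18-fold, and TMEM176B, 3.08-fold. The lowest under that rule were ZNF865, 4.11-fold lower, SLC30A3, a zinc transporter, 2.95-fold lower, and BCL2, an inhibitor of apoptosis, 2.84-fold lower (63.2 against 179.6). All of these signals were below 400 on every array. In all, 125 genes were higher and 75 lower, out of 13246 that reached the floor, and with a signal of at least 500 on the brighter array 3 were higher and 2 lower. Simulated unchanged arrays, with noise between probe sets only, gave means of 22.7 and 23.3, which are again not a rate of false calls.

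The rest of the rule's genes in that comparison were ASCL5, TSACC, GPR137, SIX5, CCDC24 and HTR4, between 2.74-fold and 3.03-fold higher, and CUEDC1, LKAAEAR1, FUT2, DOHH, CAPN6, TREML2 and ITPKA, between 2.32-fold and 2.78-fold lower. Chosen after their values were seen, the bright called genes were TAF15, an RNA-binding protein (1159 against 2686, 2.32-fold lower), ACTBP9, 2.01-fold lower, ING4, 2.35-fold higher, APBA2, 2.29-fold higher, and CLDN15, 2.03-fold higher with probe sets that disagreed. The immediate early gene NR4A1 was at least 2.66-fold higher, but its probe sets disagreed, and the median over them gave a log2 ratio of -0.090.

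Full-length LATS2 was then set against LATS2N, a comparison that leaves the control array out. On the LATS2 array ANKRD37 was 4.35-fold lower than on the LATS2N array, ADM 4.02-fold lower, DDIT4 3.60-fold lower and ALDOC, a glycolytic enzyme gene, 3.57-fold lower. PLAU, which encodes the urokinase protease, was 3.76-fold lower, TM4SF1 3.67-fold, the chemokine receptor gene CXCR4 3.11-fold, RARRES2 3.02-fold and TNFAIP2 2.97-fold. PLAU (55.4 against 208.4) and CXCR4 (92.3 against 286.5) were dim, with the LATS2 signal of PLAU close to the floor. Under the naming rule, ZNF865, 4.87-fold, CASTOR2, 4.02-fold, and HSPA6, 3.86-fold, were the highest on the LATS2 array. Their signals on the LATS2N array were dim, at 58.8, 83.3 and 81.4. In all, 78 genes were higher and 132 lower, out of 13177 that reached the floor, and at a signal of at least 500 these were 4 and 28.

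In the same comparison the hypoxia list was below 0 in 16 of 16 members, with a median of -0.67, and the NF-kB list in 14 of 14, with a median of -0.63. With settings computed after seeing the data, the hypoxia median was -0.37 with the median over probe sets, and the NF-kB median was -1.07 at a floor at the 75th percentile and -1.19 at a signal of at least 500. The sterol list was below 0 in 12 of its 16 measured members, with a median of -0.37. All 3 medians lay below all random lists. LEMD1 was 3.42-fold lower, and the other higher genes of the rule were DRC4, SLC30A3, PPFIBP2, CUEDC1, TEDC1, ANKRD20A11P and CBARP, between 2.63-fold and 3.53-fold. The Wnt target list had a median of 0.01 and the YAP and TAZ target list 0.05. The list of Hippo pathway components had a median of 0.13 at percentile 95.3 and that of beta-catenin transduction components 0.11 at percentile 91.6.

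The constructs shared 36 genes called higher and 23 called lower against control, and no gene was called in opposite directions. Under the naming rule, the shared higher genes were ASCL5, CCDC24, DNAH1, a dynein heavy chain, LZTS3, SRARP, TMEM92, TBKBP1, SPANXB1, LINC00520 and H2AC17. All of them were dim, with control signals from 53.9 for DNAH1 to 106.3 for TMEM92. The brightest signal among them was 370.2, for SPANXB1 on the LATS2 array. BCL2, 2.76-fold and 2.84-fold lower on the LATS2 and LATS2N arrays, TCP11L2 and TMEM198 were the only shared lower genes within the rule's floor and probe set limits. TAF15 was also called lower in both but fell outside them, since its probe sets disagreed in LATS2 against control. Both constructs are set against 1 control array, so some overlap arises without any effect. Simulated unchanged arrays sharing a control gave a mean of 0.53 genes called higher in both, with a range of 0 to 3, and 16.2 called lower in both, with a range of 8 to 25, the latter when a dim gene reads high on the control alone. The 23 shared lower genes lie inside that range. Independent lists of these sizes among 12826 genes give 1.24 and 0.65. Across 11535 genes above the floor on all 3 arrays, the correlation of the log2 ratios was 0.49, against a simulated 0.50, and the covariance 0.049, against a simulated 0.020. Equal noise on arrays sharing a control gives a correlation near 0.50 whatever its size, so that simulated value was fixed in advance. The simulated covariance and shared counts follow the noise put in, which leaves out differences between cultures. The excess in covariance therefore cannot tell a shared effect from a control array noisier than simulated. The size of the covariance followed the floor: it was 0.103 at the 25th percentile, 0.024 at the 75th and 0.115 with no floor, against 0.067, 0.0080 and 0.067 in the same simulated arrays, which were put through these floors after the values were seen. Genes are not independent replicates. The control array cannot be split, and part of the excess of shared higher genes may come from the shared control.

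**Figure D3:**
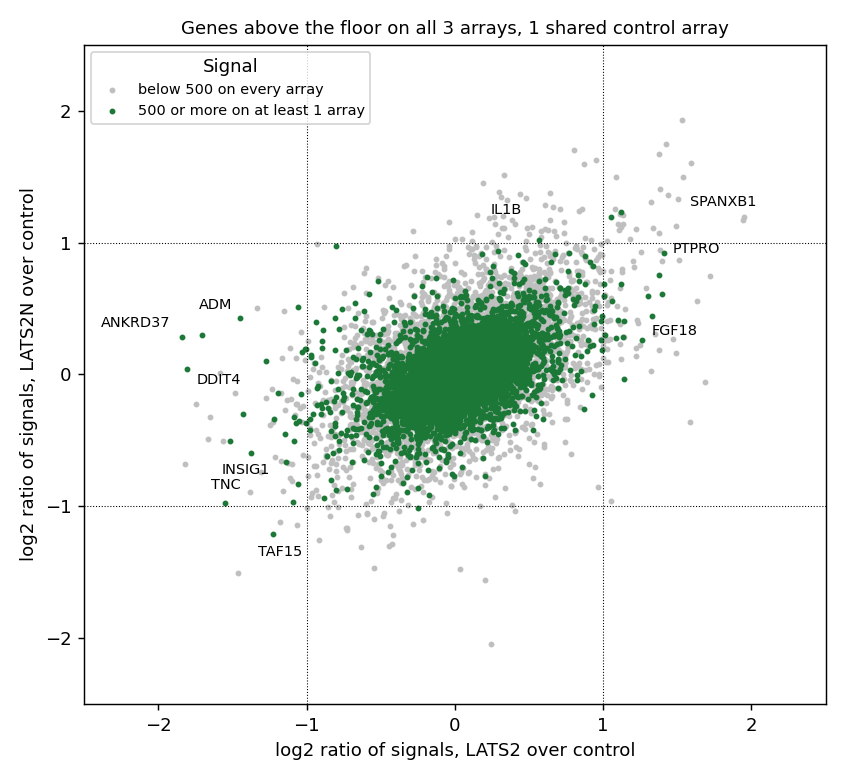
Log2 ratio of LATS2 over control (horizontal axis) against LATS2N over control (vertical axis), 1 point per gene above the floor on all 3 arrays, with dotted lines at the 2-fold call and green points for a signal of at least 500. ANKRD37, DDIT4 and ADM lie at -1.84, -1.81 and -1.70 on the horizontal axis and between 0.04 and 0.30 on the vertical one, and TAF15 lies at -1.23 and -1.21.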

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

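The tests of explanations in this part were all chosen after the results were seen. The difference between the constructs was not itself tested, since each group has 1 array: the hypoxia and glycolysis list had a median of -0.57 on the LATS2 array and 0.15 on the LATS2N array, both against control, and the NF-kB and inflammatory list had -0.55 and 0.43. These lists stand out because the 2 constructs lie on opposite sides of the control array. For the hypoxia list the LATS2N side was small. The fixed list of reference genes had a median of 0.12 on that array, at percentile 92.9.

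Array scaling or a trend with signal would move matched random lists in the same way, but the hypoxia list differed from their mean median by -0.62 and the NF-kB list by -0.61 on the log2 scale. The lists were flagged by their percentiles among such random lists, so these differences repeat the selection and are no separate test. A deviating control array alone would leave the LATS2 and LATS2N arrays alike. LATS2 against LATS2N, which leaves that array out, gave -0.67 for the hypoxia list and -0.63 for the NF-kB list. The lists were flagged because the constructs lie on opposite sides of control. A negative value here therefore follows from the selection and is no separate test either. The state of the single culture behind each array also stays open. With 1 culture per group, cell density, oxygen or medium age in the dish cannot be told apart from the construct. A biological explanation, that full-length LATS2 lowers hypoxia-induced and NF-kB target genes and the fragment without the kinase domain does not, is a hypothesis and is likewise untested. Replicate cultures at matched density and oxygen, with a kinase-dead full-length LATS2 beside the fragment, would decide between these, and the 3 arrays hold neither.

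The sterol and fatty acid synthesis list was lower on both construct arrays. Scaling or a trend with signal would move matched random lists alike, and the list median differed from their mean by -0.68 on the LATS2 array. The list was picked after its percentile among such random lists was seen, so this is no separate test. A deviating control array as the whole cause on the LATS2 array would leave LATS2 against LATS2N near 0, and that median was -0.37. For the LATS2N array, where the median was -0.27, the same explanation stays open, because every value for it uses that control array, and the 18S ribosomal RNA probe sets set that array apart in the same order, with median log2 ratios of -1.31 for LATS2 and -0.70 for LATS2N. A difference in culture medium or density, which sterol genes follow, and an effect of the constructs also cannot be told apart here.

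Outside the gene results, 3 probe sets without a single gene name were more than 4-fold above the control array. The first read 24.8, 25.6 and 310.0 on the control, LATS2 and LATS2N arrays, a floored log2 ratio of at least 2.62 for LATS2N. The second read 1649, 5539 and 6770, with 2.04 for LATS2N, and the third read 55.9, 335.1 and 188.2, with 2.58 for LATS2.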

How the results depend on the processing

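Signal over background limits the counts: with 1 array per group, most called genes were dim, and their number followed the floor and the size of the call. In the order higher and lower for LATS2 against control, higher and lower for LATS2N against control, higher and lower for LATS2 against LATS2N, and shared by both constructs, the counts were 127, 111, 125, 75, 78, 132 and 59. Centred arrays and quantile normalisation kept each of them within 1.5 times, and so did leaving out probe sets with possible shared targets. A floor at the 25th percentile gave 813, 949, 870, 779, 744, 979 and 638, a floor at the 75th percentile 9, 19, 0, 1, 0, 20 and 1, and no floor with 16 added 550, 687, 575, 576, 547, 685 and 357. Calls at 1.5-fold gave 772, 582, 644, 433, 564, 668 and 416, calls at 3-fold 11, 14, 11, 3, 8, 15 and 3, and calls from 2 probe sets 5, 10, 2, 4, 2, 9 and 0. A signal of at least 500, added after seeing the data, gave 17, 27, 3, 2, 4, 28 and 3. The median over probe sets moved 3 counts past 1.5 times: 73 lower for LATS2 and 80 higher for LATS2N against control, and 79 lower for LATS2 against LATS2N. Another floor percentile, another size of call and the minimum signal loosen or tighten the call by construction. With no floor, with the median over probe sets and with 2 probe sets the called genes also differed, and the cause was not tested: of the 111 genes lower on the LATS2 array, 86, 48 and 6 were called there too.

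The hypoxia, sterol and NF-kB medians kept their sign in every setting, those of LATS2 against LATS2N being computed under other settings only after seeing the data. The hypoxia median was -0.32 for LATS2 against control and -0.37 against LATS2N with the median over probe sets, and 0.28 for LATS2N against control and -0.77 for LATS2 against LATS2N without probe sets of possible shared targets. The sterol median of LATS2 against LATS2N was -0.29 at the higher floor and at a signal of 500, -0.26 with the median over probe sets and -0.29 without shared targets. The NF-kB median was 0.32 and 0.31 for LATS2N in these last 2 settings, -0.67 for LATS2 at a signal of 500, and -1.07 and -1.19 for LATS2 against LATS2N at the higher floor and at a signal of 500. The YAP and TAZ median of LATS2 against control was 0.10 at the lower floor and 0.076 with no floor; the cause was not tested. Of the named genes, NR4A1 on the LATS2N array reversed to -0.090 with the median over probe sets, which take in its disagreeing probe sets. All 91 values of named genes stayed within the spread between probe sets under centred arrays, quantile normalisation, the lower floor and no floor. Much of this follows by construction. Most named genes had to have both signals above the floor, so a lower floor leaves their ratios unchanged. Centring shifted the LATS2 and LATS2N arrays by only 0.038 and 0.022 on the log2 scale. The higher floor, which shrinks the ratios of dim genes by construction, moved 81 of the 91 past the spread between probe sets. The median over probe sets moved 41 besides the 1 reversed. Without shared targets 10 moved, 65 did not, and 16 could not be computed because the gene had no probe set left. The covariance between the constructs moved past 1.5 times under the lower floor, the higher floor and no floor, while the correlation did not under any of the 7 settings.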

Other observations

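The families and tests in this part were chosen after the values were seen. Transcripts of the mitochondrial genome were higher on both construct arrays than on control. All 7 measured transcripts had ratios above 0, with a median log2 ratio of 0.65 on the LATS2 array and 0.48 on the LATS2N array. Each median lay above all matched random lists, and every ratio stayed above 0 under centred arrays and quantile normalisation. The 7 transcripts come from the same genome and may move together, so they are not 7 separate observations as the genes of random lists are taken to be. Both comparisons use the same control array, so their agreement can come from that array alone. In LATS2 against LATS2N, which leaves it out, all 7 ratios were again above 0, with a smaller median of 0.17 at percentile 99.94. COX1, a subunit of cytochrome c oxidase, read 7623 on control, 16544 on LATS2 and 12230 on LATS2N, and ND4, a subunit of complex I, read 15440, 24341 and 21516. The 18S ribosomal RNA probe sets differed the other way, brighter on the control array by a median of 2.48-fold over LATS2 and 1.63-fold over LATS2N.

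Metallothioneins, small proteins that bind zinc and copper, differed in direction between the constructs, less far from the random lists than the NF-kB list. All 7 that reached the floor were lower on the LATS2 array than on control, with a median log2 ratio of -0.23 at percentile 0.35, and all 7 were higher on the LATS2N array, with a median of 0.15 at percentile 97.88. The directions were the same under centred arrays and quantile normalisation. The setting without probe sets of possible shared targets was not run for this family. The 7 members may therefore not be separate measurements, unlike the genes of the random lists. Between LATS2 and LATS2N the median was -0.40, below all random lists, from -0.62 for MT1F to -0.21 for MT1HL1.

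Neighbouring genes were examined in windows of 40 along each chromosome, in the gene order of GRCh38.p14. On the LATS2 array against control, the highest window lay on chromosome 17, from BRCA1 to MAPT, with a median log2 ratio of 0.39, and another on chromosome 14, from POMT2 to RIN3, reached 0.32. Chance order of the genes is argued against by 0 of 1000 shuffles with a window as high as that on chromosome 17, where the highest shuffled window was 0.31. A deviating control array is argued against by a median of 0.27 for the same window in LATS2 against LATS2N, the highest of that comparison, which 1 of 1000 shuffles reached, with a highest shuffled window of 0.30. An extra copy of the segment in the LATS2 line stays an untested hypothesis. That 34 of the 40 genes lay above the median of all genes follows from choosing the highest window and does not bear on it, and regulation shared by neighbours cannot be told apart from an extra copy without DNA from the line. In LATS2N against control no window exceeded the shuffles.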
